A study of Drosophila melanogaster with 2 samples.

How the data were processed

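Chromatin from *Drosophila melanogaster* embryos expressing an Ada2b-eGFP fusion was sonicated to fragments of 200 to 800 bp and precipitated with an antibody to GFP, per the labels. The labels give 2 biological replicates of 1 group. Of the 8 deposited peak lists, 4 belong to the series and 2 to each replicate, and they are of 2 kinds: ranked lists of all candidate peaks, and lists thresholded on the irreproducible discovery rate (IDR), which measures how well peak ranks repeat. Per the file headers and notes deposited by the authors, peaks were made from alignments to dm6 with a control file, on both replicates for the series lists and on a single replicate for the others. The aligner, the peak caller and their versions are not given in the sources used here. The control was not analysed here.

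The deposited score of each peak is the IDR rescaled by the authors, and its lowest value in each thresholded list was 830. The deposited signal of each peak is a score from the authors' peak caller, not normalized between lists, and it was used only to rank and describe peaks within a list. The deposited −log10 values are a −log10 q from the peak caller and, in the ranked lists, a −log10 IDR. The lowest −log10 IDR in the conservative list was 2.00. The column of replicate signals in the ranked list was assigned to replicates by its values: 99.6% of the first column's values past the threshold were found in replicate 1's own ranked list and 99.2% of the second column's in replicate 2's. Depth per sample is not known from these lists, so precision rests on the number of peaks.

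Coordinates are those of dm6, and no peak extended past the end of an arm of the reference genome (NCBI Release 6). Genes were taken from Ensembl release 115. Peaks on the 7 arms were used, which left out 1 peak of the conservative list, on a scaffold outside the arms. A promoter peak was one with its summit within 500 bp of any annotated TSS of a protein-coding gene, and a peak counted for every such gene. Shuffles moved summits at random within their arm 1000 times, and resampling tests used 100000 draws without replacement. Location classes were assigned in the order promoter, 5' UTR, coding sequence, 3' UTR, intron and outside protein-coding genes. The chance level of replicate overlap came from shuffled summits in the other replicate's peaks, widened by the median peak's radius. Gene lists, chromosome arms and motifs were tested with two-sided Fisher's exact tests. Motif controls were genes without a peak or, away from promoters, 5 windows per peak matched on arm and on GC content within 2 percentage points. P-values were adjusted by Benjamini and Hochberg within each family, and 0.05 was the threshold. Intervals are 95% Clopper-Pearson, and a count of 0 is given with the share that 3 counts would make. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

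The 39 gene lists (complexes, housekeeping genes, histones, developmental regulators, inducible genes, cell type markers and genes of late tissues), the 24 motifs, the tests and most alternatives were chosen before the data were examined. Lists with under 5 measured members were not tested, which left 38. Chosen after the data were examined were 6 replacements of renamed gene symbols, the removal of 3 genes that a name pattern had wrongly placed (Cp190 from chorion genes, Acp1 and Acp65Aa from male accessory gland genes), and 2 added alternatives: the peaks past the IDR threshold that the thresholded list lacks, and 1 peak per replicate peak. The named genes were, by rule, the gene nearest to each of the 25 strongest promoter peaks found in both replicates, up to 3 members of each list with the strongest promoter peak, or up to 2 members of a list with none, every SAGA subunit, and the 5 strongest peaks away from promoters, and the report gives a selection of them. Other alternatives were the other thresholded list, the stronger peaks, each replicate alone, other TSS windows, overlap of the whole peak, the most 5' TSS, the nearest gene, other overlap rules and other motif windows.

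The tests were tested on simulated data. A list of the size and rate of the ribosomal protein genes was recovered in 96 of 100 runs, and 2 of 3700 unplanted lists were called. In these runs each gene was drawn independently. Peaks counted for several neighbouring genes were not simulated, so the rate of false calls with such peaks is not known. Summits with a share placed at starts were called in 10 of 10 runs. Random summits were called in 4 of the first 40 runs, and the runs were then extended to 200, of which 10 (5%) were called. A planted motif was recovered and 0 of 23 others were called. For the signal of gene lists, a first single simulated shift of 60 was not called, and a larger shift was called. Repeats at 5 sizes on the real promoter peaks followed: 0 of 20 runs were called with no shift, 1 of 20 at 30, 11 of 20 at 60, 20 of 20 at 100 and 20 of 20 at 150, and 10 of 1200 tests of other lists were called. At a shift of 60 the list's median stood about 23.1 percentiles above 50.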

Results

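Anti-GFP chromatin immunoprecipitation and sequencing was used to map Ada2b in *Drosophila melanogaster* embryos aged 0 to 18 h. Ada2b is an ADA2 subunit of SAGA, a coactivator complex that carries the Gcn5 histone acetyltransferase and a histone H2B deubiquitinase, and of other complexes of Gcn5. The embryos expressed an Ada2b-eGFP fusion, and 2 biological replicates made up the single group. With 1 group there was no comparison between conditions, and the peaks were compared between replicates, with shuffled positions and with annotated genes. The conservative list of peaks held 4797 peaks on the dm6 assembly, of which 4796 lay on the main chromosome arms. It covered 1.34 Mb with a median peak width of 310 bp. Replicate 1 alone gave 3762 peaks and replicate 2 alone gave 3020. Peak signal, the value given by the authors' peak caller, had a median of 86.1 in the conservative list, with the 10th percentile at 49.8 and the 90th at 244. Read depth was not analysed here, and intervals below cover counting error only.

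The same sites were largely recovered in both replicates. Of replicate 1's 3761 peaks on the main arms, 2484 (66.0%, 95% Clopper-Pearson interval 64.5 to 67.6) shared at least 1 bp with a replicate 2 peak, against 1.27% of shuffled peaks. Of replicate 2's 3019 peaks, 2472 (81.9%, interval 80.5 to 83.2) shared at least 1 bp with a replicate 1 peak, against 1.56% after shuffling. The mean of both directions was 74.0%. The 2 directions describe 1 overlap and differ mainly through list length, so they give no spread between replicates. In each direction the one-sided permutation p was 0.000999, the smallest that 1000 shuffles can give. Across the 91420 peaks of the ranked list that pairs the replicates, the signals had a Spearman rho of 0.302 and a Pearson r of 0.544 on the log2 scale. Among the 4902 peaks past the IDR threshold rho was 0.783 and r was 0.877. These correlations run across peaks, which are not independent replicates, and the second set was selected for reproducibility.

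Ada2b-eGFP peaks were concentrated at the starts of protein-coding genes. Of the 4796 summits, 1959 (40.8%, Clopper-Pearson interval 39.5 to 42.3) lay within 500 bp of an annotated protein-coding transcription start site (TSS), against a mean of 11.5% for shuffled summits, a ratio of 3.55. The share was 41.6% in replicate 1 and 45.9% in replicate 2 (43.7% ± 3.02, SD, n = 2). The one-sided permutation p was 0.000999, the smallest possible. Introns held 39.2% of summits against 39.4% after shuffling, a difference that did not pass the test (two-sided permutation p adjusted over 6 classes, 0.857). In replicate 2 alone introns held 36.97%, 0.940 times the shuffled share, which passed (adjusted permutation p = 0.0144). Coding sequence held 0.709% against 13.9%, and 3' UTRs held 0.855% against 4.53%. Sequence outside protein-coding genes held 17.9% against 29.9%. For promoters, coding sequence, 3' UTRs and sequence outside genes the two-sided adjusted permutation p was 0.003, from the smallest p that the shuffles can give. Summits in 5' UTRs beyond 500 bp from a TSS made up 0.5% against 0.789% (adjusted permutation p = 0.0264), a call that was lost in 4 of 6 alternative settings, among them without replicate 2 (adjusted permutation p = 0.0863).

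**Figure D1:**
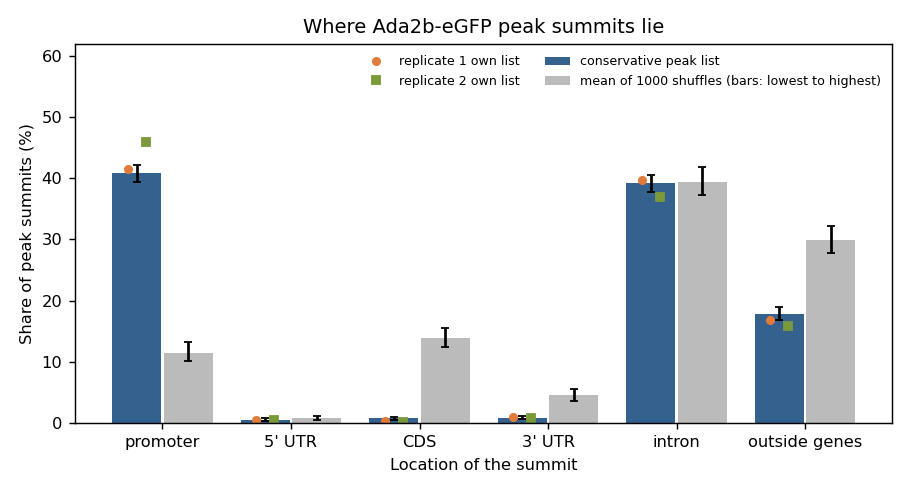
Share of peak summits (percent, vertical axis) in each location class for the conservative list (blue bars, 95% Clopper-Pearson intervals) and for 1000 shuffles (grey bars, mean with lowest and highest), with replicate 1 as circles and replicate 2 as squares. Promoters held 40.8% of summits against a shuffled mean of 11.5%, and coding sequence held 0.709% against 13.9%.

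The strongest promoter peak lay at Ugalt (FBgn0024994), a UDP-galactose transporter gene, at X 2703729 to 2704046, with the summit 31 bp upstream of the TSS, a signal of 2109 and the summit sequence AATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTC. It was followed by mRpL41 (FBgn0034001), a mitochondrial ribosomal protein gene, at 2R 15217597 to 15217906 with a signal of 1791, and by CG14100 at 3L 19590468 to 19590774 with 1740. CG7601 (1594), PNPase (1396) and CenG1A (1360) came next. The 25 strongest promoter peaks found in both replicates also included mRpS10 (1269) and mRpL23 (818), eIF6, a factor of ribosomal subunit biogenesis (1183), Chro, a chromodomain protein of interbands (1045), and gish, a casein kinase (1014). The gene with the nearest TSS is named here. Several of these peaks lay within 500 bp of a second gene's TSS, as between CenG1A and mRpS23 or between Arl1 and brm, and their signal could not be assigned to either.

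Promoter summits lay upstream of the start site. Their median position was -113 bp, with quartiles at -197 and -43.5 bp, and 343 of the 1958 summits not at position 0 (17.5%, Clopper-Pearson interval 15.9 to 19.3) lay downstream (two-sided exact binomial p = 8.46e-197). The share downstream was 17.03% in replicate 1 and 14.5% in replicate 2. The binomial test takes equal shares as its null. Positions around starts were not compared with shuffled summits, so the layout of neighbouring genes is not accounted for. Promoter peaks ranked above other peaks in signal. The median percentile was 55.8 for the 1959 promoter peaks and 46.3 for the 2837 others, a difference of 9.49 percentiles (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Of the 100 strongest peaks, 64% lay at a promoter.

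**Figure D2:**
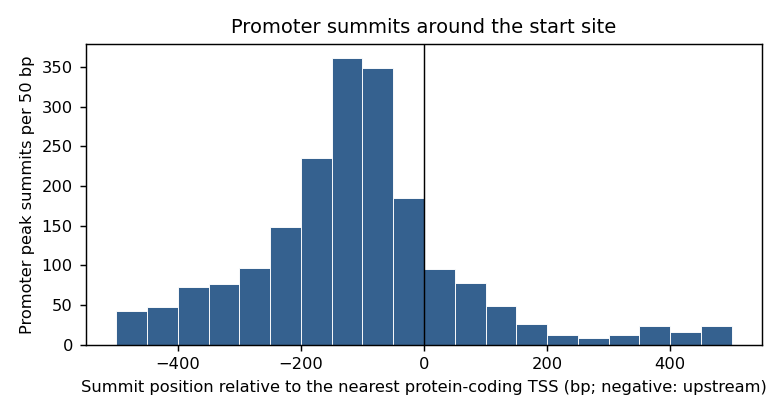
Number of promoter peak summits per 50 bp bin (vertical axis) by position relative to the nearest protein-coding TSS (horizontal axis, bp, negative upstream) for the 1959 promoter peaks of the conservative list. The median summit lies at -113 bp.

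A promoter peak was found at 2444 of 13968 protein-coding genes (17.5%). Replicate 1 gave 1983 such genes, replicate 2 gave 1842, and 1507 were found in both. Of the 1959 promoter peaks, 685 lay within 500 bp of the TSS of more than 1 gene and were counted for each. Genes that share a peak are not independent, so Fisher p-values over genes can be too small.

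Genes of the SAGA complex included Ada2b itself. Its peak lay at 3R 8240080 to 8240218, with the summit 361 bp downstream of a TSS and a signal of 161, at percentile 71.5 among genes with a promoter peak. Over the replicates the percentile was 64.0 ± 16.1 (SD, n = 2). The flies were transgenic for Ada2b-eGFP and the control was not analysed. Signal from transgene copies therefore cannot be told apart from binding at Ada2b, which is counted among the SAGA members below. Gcn5, the acetyltransferase, had a signal of 265 (replicate percentile 82.6 ± 3.60, SD, n = 2) and wda, a SAGA structural subunit, had 176 (67.5 ± 5.11). Peaks also lay at e(y)2 (111), Atxn7 (74.3), Ada3 (74.0), Sf3b3 (65.3) and Sgf11 (46.8). In the lists of single replicates, Atxn7 and Ada3 had a promoter peak in replicate 1 only, Sf3b3 in replicate 2 only and Sgf11 in neither. The conservative list held 8 of 21 measured members, 38.1% against 17.5% of other genes, which did not pass the threshold over all lists (odds ratio 2.91, two-sided Fisher's exact test, adjusted p = 0.0866). It passed when only the most 5' TSS of each gene was used (adjusted Fisher p = 0.0494). The conservative list held no promoter peak at Sgf29, which had one in replicate 1 alone (signal 48.99), and neither this list nor that of either replicate held one at Ada1-1, Ada1-2, Nipped-A, Saf6, Sf3b5, Spt20, Spt3, Spt7, Taf10b, Taf12, Taf9 or non-stop (not). None of the 9 measured members of ATAC, a Gcn5 complex that contains Ada2a rather than Ada2b, had a promoter peak, which allows a share of up to 33.3% (adjusted Fisher p = 0.528).

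Genes for cytosolic ribosomal proteins carried promoter peaks more often than other genes. Of 93 members, 38 had a peak (40.9% against 17.3%, odds ratio 3.29, two-sided Fisher's exact test adjusted over 38 lists, p = 1.06e-06). The count was 47 in replicate 1 and 25 in replicate 2 (38.7% ± 16.7, SD, n = 2). RpL32 had a signal of 327 (replicate percentile 88.1 ± 1.01, SD, n = 2), RpL41 had 233 (71.1 ± 19.5) and RpL34b had 223 (76.0 ± 5.83). Genes of insulator and promoter factors were bound at 8 of 16 (50%, odds ratio 4.73, adjusted Fisher p = 0.0186), among them Chro (1045), Cp190 (321), a cofactor of insulator proteins, and Trl (230), which encodes GAGA factor. That call was lost in replicate 2 alone (adjusted Fisher p = 0.0610) and when each peak was counted only for the gene with the nearest TSS (0.211).

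Several other groups used by most cells did not pass the threshold. Mitochondrial ribosomal proteins had a peak at 20 of 73 genes (27.4%, adjusted Fisher p = 0.106), with mRpL41, mRpS23 and mRpS10 highest. Translation factors had 16 of 53 (adjusted Fisher p = 0.104), led by eIF6, eEF1gamma (262) and eIF3c (169). The spliceosome had 11 of 34 (adjusted Fisher p = 0.119), including U2af50 (302), snRNP-U1-C (207) and SNRPG (181). Cell cycle and replication genes had 11 of 35 (adjusted Fisher p = 0.123), including Dp (305), dpa (178) and CycE (133). RNA polymerase II subunits had 5 of 13 (adjusted Fisher p = 0.156), with Polr2B at 224 and Polr2H at 218, Mediator had 8 of 29 (p = 0.299), with MED27 at 280 and MED30 at 260, and TFIID had 3 of 16 (p = 0.834), with Taf5 at 236. Proteasome subunits had 7 of 48 (adjusted Fisher p = 0.834), with Rpn3 at 231, and the respiratory chain and ATP synthase had 13 of 85 (p = 0.820), with ND-ASHI at 364. These tests were two-sided. With the most 5' TSS alone, mitochondrial ribosomal proteins passed (adjusted Fisher p = 0.0494), and with the nearest TSS alone, translation factors passed (0.0402).

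Cuticle protein, adult chemoreceptor and male accessory gland genes carried promoter peaks less often than other genes. None of 121 cuticle protein genes (up to 2.48% allowed by a count of 0, adjusted Fisher p = 2.23e-09) and none of 120 adult odorant and gustatory receptor genes (up to 2.50%, adjusted Fisher p = 2.23e-09) had one. Among 45 male accessory gland genes only Sfp26Ad had a peak (signal 88.5, found in replicate 1 alone but not in replicate 2, adjusted Fisher p = 0.0186), and this call was lost in 3 of 11 alternative settings, among them without replicate 2 (0.0784). None of the 111 replication-dependent histone genes had one (up to 2.70%, adjusted Fisher p = 8.72e-09), but these genes are near-identical tandem copies whose reads cannot be placed uniquely, so this value is uncertain. Testis genes had 1 of 37, Tektin-C (48.1, found in neither replicate alone, adjusted Fisher p = 0.0705), and passed with the other thresholded list (adjusted Fisher p = 0.00735) and without replicate 2 (0.0461). No peak was found for 14 chorion and vitelline membrane genes (adjusted Fisher p = 0.299), 19 larval gut proteases (0.156) or the 3 yolk protein genes, which were too few to test.

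Patterning genes and markers of embryonic cell types did not pass the test. Embryos of 0 to 18 h mix ages and cell types, so binding in few cells or for a short time could be missed. No gap or pair-rule gene of 25 had a promoter peak in the conservative list (up to 12%, adjusted Fisher p = 0.0705) and 1 had one in replicate 1 alone. The difference passed with a 1000 bp window (adjusted Fisher p = 0.0323) and with any overlap of the peak with the TSS window (0.0478). Dorsoventral patterning genes had 1 of 22, htl (79.6, not found in replicate 2 alone, adjusted Fisher p = 0.299), and proneural and neuroblast factors 1 of 18, scrt (85.2, adjusted Fisher p = 0.505). Hox genes had 2 of 8, Dfd (87.6) and Antp (38.1, found in neither replicate alone), with an adjusted Fisher p of 0.805. The E(spl) and Bearded complexes, targets of Notch signalling, had 3 of 15 (adjusted Fisher p = 0.834), with E(spl)m3-HLH highest at 185. Signalling components had 4 of 28 (adjusted Fisher p = 0.851), with spi, an EGF receptor ligand, at 280. Polycomb group genes had 4 of 20 (adjusted Fisher p = 0.834), with ph-p at 637 and E(z) at 238. Neuronal genes had 1 of 21, elav, an RNA-binding protein used as a neuronal marker (558, adjusted Fisher p = 0.299).

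Glial genes had 3 of 9 (adjusted Fisher p = 0.342), with moody, a receptor of the blood-brain barrier, at 564. Muscle genes had 2 of 23, sls (245) and mbc (151), with an adjusted Fisher p of 0.555. Germ line genes had 5 of 18 (adjusted Fisher p = 0.358), with orb at 259 and bgcn at 156. Fat body genes had 1 of 9, Adh (60.9, not found in replicate 2 alone), and gut regulators 1 of 9, tin (277), each with an adjusted Fisher p of 1. None of 14 haemocyte genes (adjusted Fisher p = 0.299) and none of 5 dosage compensation genes (0.779) had a peak. Heat shock genes had 5 of 16 (adjusted Fisher p = 0.324), with Hsp27 at 669 and Hsp26 at 177. Ecdysone response genes had 4 of 14 (adjusted Fisher p = 0.436), with E23 at 454 and Eip75B at 156. Replication-independent histone genes had 2 of 5, His2Av (152) and His3.3B (84.8, not found in replicate 1 alone), with an adjusted Fisher p of 0.351.

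**Figure D3:**
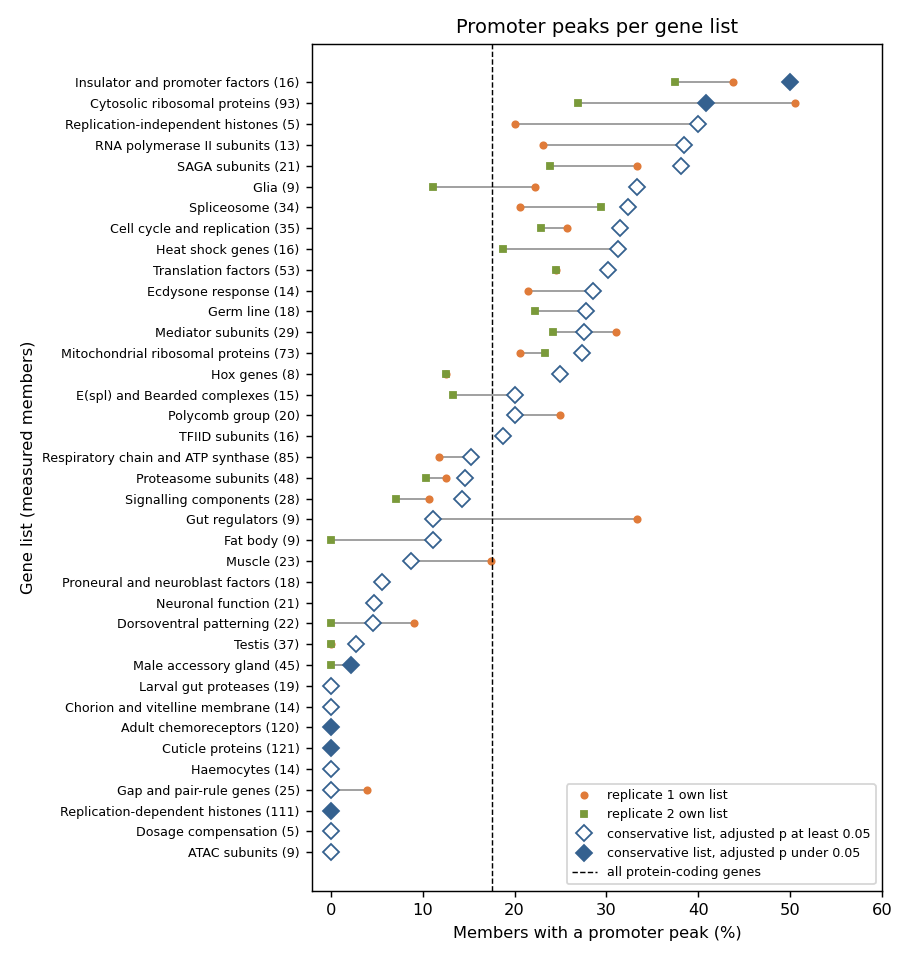
Share of each list's measured members with a promoter peak (percent, horizontal axis), for the conservative list (diamonds, filled where the adjusted two-sided Fisher p is under 0.05) and for replicate 1 (circles) and replicate 2 (squares), with the number of members in brackets and all protein-coding genes at 17.5% (dashed line). Cytosolic ribosomal proteins stand at 40.9% and cuticle proteins at 0.

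Bound members of the 13 lists with at least 5 such genes did not stand apart in signal. Cytosolic ribosomal protein genes had a median percentile of 50.2 (adjusted permutation p = 0.999) and SAGA genes one of 41.6 (0.854). The extremes were heat shock genes at 71.4 and cell cycle genes at 34.5 (adjusted permutation p = 0.854 for both), and 0 lists passed at an adjusted or an unadjusted p of 0.05 (two-sided permutation tests). Small shifts were not detectable. In simulations on the 38 bound ribosomal protein genes, a shift of 30 in signal was called in 1 of 20 runs. A shift of 60 was called in 11 of 20 and a shift of 100 in 20 of 20. The list's median stood about 11.9 percentiles above 50 at a shift of 30 and about 23.1 at a shift of 60. Lists with fewer bound genes were not simulated.

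Promoter peaks were unevenly spread over the chromosome arms. On 3L, 520 of 2739 genes had one (18.99% against 17.1% on other arms, adjusted Fisher p = 0.0415), and on X 345 of 2196 (15.7% against 17.8%, 0.0415). The 4th chromosome, which is rich in heterochromatin, had 4 of 80 (5%, Clopper-Pearson interval 1.38 to 12.3, adjusted Fisher p = 0.0115), and Y had 0 of 23 (interval up to 14.8%, 0.0415). The tests were two-sided and adjusted over 7 arms. Arms 2L (17.8%), 2R (16.8%) and 3R (18.2%) did not pass. The lower share on X concerns genes with a promoter peak, not peaks at all sites. Of all peaks on the arms, X held 928 (19.3%), against 897 on 2L, 844 on 2R, 1022 on 3L and 1099 on 3R. Peak counts per arm were not tested. Each of the 4 calls was lost in some settings: without replicate 2 the adjusted Fisher p was 0.0861 for the 4th chromosome and 0.114 for Y, in replicate 2 alone it was 0.111 for Y, with the other thresholded list it was 0.119 for X, and with a 250 bp window it was 0.119 for 3L. Of the 106 peaks past the IDR threshold that the conservative list lacks, 65 lay on 3R. With these peaks added, an alternative chosen after the data were seen, 3R passed (odds ratio 1.13, adjusted Fisher p = 0.0320) and 3L did not (0.0634).

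Sequence elements near the most 5' TSS differed between the 2444 genes with a promoter peak and the 11524 without. Of the 24 motifs, sought on either strand at any position, 11 passed in windows of 150 bp each side. Fisher's test treats genes as independent, but neighbouring genes can share a peak and part of a window. The p-values here can therefore be too small. Ohler motif 7 was found at 16.4% against 7.26% (odds ratio 2.51, two-sided Fisher's exact test, adjusted p = 7.44e-40). The DRE, bound by Dref, was found at 11.7% against 7.84% (adjusted Fisher p = 9.24e-09), CAGCTG at 22.995% against 17.01% (7.43e-11) and the M1BP site at 7.61% against 5.35% (8.27e-05). The Initiator was less frequent at genes with a peak (29.3% against 37.7%, adjusted Fisher p = 3.67e-14), as was the TATA box (16.6% against 19.9%, 0.000422), although the TATA box call was lost with windows of 250 bp (0.319). The same searches hit 26.1% (Initiator) and 16.3% (TATA box) of matched windows away from promoters. Many hits therefore need not be working core promoter elements. The Myc/Max E-box, Mef2 and Antennapedia-class sites and GAGA were more frequent and the Bicoid-class site less frequent, each with an odds ratio between 0.716 and 1.40. The calls for GAGA, Mef2 and the Antennapedia-class site were lost with windows of 100 bp (adjusted Fisher p = 0.122, 0.859 and 0.609), GAGA also among genes with a single TSS (0.671) and Mef2 also without replicate 2 (0.0732).

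The 2837 peaks away from promoters lay a median of 3193 bp from the nearest protein-coding TSS (quartiles 1331 and 7786 bp). The strongest lay in an intron of CG11050 (FBgn0031836) at 2L 6612545 to 6612879, with a signal of 1868, 1019 bp from a TSS of that gene. The next lay in introns of ph-p, a Polycomb group gene, at X 2137194 to 2137521 (1410), with the summit only 508 bp from a TSS of ph-p and so just outside the promoter window, and of CG32772 at X 4910229 to 4910529 (1223), 1257 bp from its TSS. They were followed by intergenic peaks at 3R 16222358 to 16222620, 3163 bp from the TSS of tara (1155), and at 2R 13035199 to 13035460, 11925 bp from that of CG13323 (1146). All 5 were found in both replicates. Against windows matched on arm and GC content, GAGA was found at 6.06% against 3.31% (odds ratio 1.89, adjusted Fisher p = 1.01e-09), the Pho site at 6.59% against 9.07% (0.000134) and the Bicoid-class site at 7.86% against 10.4% (0.000146, two-sided). In all, 9 of 24 motifs passed with windows of 150 bp each side, but only the Bicoid-class site passed with windows of 100 bp, where the Pho site had an adjusted Fisher p of 0.0518 and GAGA had an odds ratio of 1.13 (0.557). GC content was matched over the whole window only, and mean GC was 31.7% at these summits and 44.1% at 150 bp from them. Local composition is therefore not accounted for in these calls.

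Long noncoding RNA genes had summits near their TSS more often than shuffled summits gave. Of 1945 such genes, 125 had one against a mean of 71.1 after shuffling (ratio 1.76, one-sided permutation p adjusted over 5 classes, 0.005, from the smallest p possible), and for 32 of the 125 the summit also lay within 500 bp of a protein-coding TSS. The shuffles did not keep the concentration of peaks at protein-coding starts. How far the excess follows from protein-coding starts nearby is therefore not accounted for. The strongest of these summits belonged to lncRNA:CR44463 (1791), which is the peak of mRpL41, and to lncRNA:CR44619 (1066). The counts for tRNA genes (15 of 290, adjusted permutation p = 0.330), snRNA genes (2 of 32, 0.415), snoRNA genes (12 of 269, 0.415) and miRNA genes (6 of 260, 0.861) did not pass.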

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

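All tests in this part were chosen after the result was seen. Peaks past the IDR threshold in the ranked lists but missing from the thresholded lists, which the comparisons above use only in an added alternative, numbered 106 for the conservative list and 109 for the other thresholded list.

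Of the 106, 65 lay on 3R, 31 on 2L, 7 on 3L and 3 on 2R. The strongest lay in an intron of ush at 2L 480932 to 481255, with a signal of 1904, the second highest among all passing peaks, and others lay in Lk6 (1215), at larp (850), in trx (692) and near tara (619). Weak signal is argued against, since their median percentile among passing peaks was 51.3. Only 5 of the 106 (4.72%) overlapped an annotated transposable element, although this share was higher than the 0.751% of kept peaks. The low share argues against a filter on such elements for most of the missing peaks. They were clustered: for 68.9% the nearest passing peak was missing too, against a mean of 4.40% and a maximum of 13.2% in 1000 random draws on the same arms (one-sided permutation p = 0.000999, the smallest possible), so a filter on whole regions may account for them, and the file notes name a further parent file for the thresholded lists that the ranked lists lack. What that file holds was not seen here, and no biological explanation was tested.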

How the results depend on the processing

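No test called in the main setting changed its direction in any setting run, and only such tests could be counted as reversed. Of 533 comparisons of a named gene's signal percentile, 226 moved beyond the SD of its replicates or had no SD to compare with. The median summit position, -113 bp, changed in 5 of 6 settings, to between -126.5 and -112 bp. The share of summits near a TSS was lowest with a 250 bp window (32.1%) and highest with a 1000 bp window (50.9%) among 11 settings, each with the smallest permutation p possible. The number of called gene lists was between 5 and 7, and cytosolic ribosomal proteins were called in all 11 settings. An item called in neither setting was counted as the same, since it had no direction to keep. The number of called arms fell from 4 to 2 with the other thresholded list, with the stronger peaks and with a 250 bp window, and was 2 to 3 with one replicate left out; the cause was not tested. The number of peaks was 2398 among the stronger peaks, by construction, and 3020 to 3762 with one replicate left out. For the signal of gene lists, 1 list passed among the stronger peaks, mitochondrial ribosomal proteins (adjusted permutation p = 0.0475), and the cause was not tested. Motifs away from promoters fell from 9 called to 1 with windows of 100 bp, and the cause was not tested. Rank correlation was 0.783 among peaks past the IDR threshold, a set selected for it. With 2 replicates, leaving one out uses the other's own peak list, and no paired analysis was possible because there is 1 group.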

Other observations

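Tests of base composition and orientation of the words below, and both tests of low-signal peaks, were chosen only after the result was seen. Genes with head-to-head starts, where a start faces another gene's start within 1000 bp, carried promoter peaks more often: 855 of 1788 genes with a peak (47.8%), each peak counted for its nearest gene, against 4058 of 12180 other genes (33.3%, odds ratio 1.83, two-sided Fisher's exact test, p = 4.77e-32). Members of developmental and cell type lists were not called as holding peaks inside the gene away from starts more often than shuffled peaks gave. Of these lists, 0 passed (two-sided permutation test, adjusted p = 1 for each list). Among signalling components 12 of 28 genes had such a peak against a shuffled mean of 9.30, and among neuronal genes 5 of 21 against 8.97. Before adjustment the lowest permutation p of the developmental and cell type lists was 0.0799, for neuronal genes. After adjustment over all lists, a single list could not pass even at the smallest two-sided p of the shuffles, 0.002. The lack of a call therefore does not show absence.

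Words around CACTG were frequent beside summits: away from starts, on 3L and 3R, 384 of 1228 windows (31.3%) held 1 of 10 words of 8 bases, such as CACTGAGA, chosen from 6288 on 2L, 2R and X, against 5.93% of windows matched on arm and GC content, although windows on all arms had been looked at before, and 385 of 1959 promoter windows (19.7%) held one too. The ratio of 5.27 (Fisher p = 1e-121) argues against GC content of the whole window, the orientation to the summit kept by 377 of 427 occurrences (88.3%, two-sided exact binomial p = 3.66e-63) against words picked by chance, and the 2.87% of windows sharing a stretch of 30 bases against a dispersed repeat. Local composition was not matched: away from starts, mean GC was 31.7% at the summit and 44.1% at 150 bp from it. Annotated start sites are argued against at promoter peaks, where 24 of 460 words lay within 20 bp of a start, 0.876 times the random count (two-sided permutation p = 0.573), but unannotated ones stay open: TCAGTG was 3.15 times as frequent within 10 bp of annotated starts as 40 to 60 bp upstream (Fisher p = 4.78e-20), which decides nothing here, since TCAGTG shares the core of the Initiator and no peak enters that test. The strongest example is TCAGTGCA at 2L 6612777 to 6612784, in the intron of CG11050, 75 bp from the summit. The words may belong to a factor or a start site beside these peaks, a hypothesis found and tested on the same data, and no biological explanation other than start sites was tested.

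Peaks with a pooled signal under 20, a limit set after seeing the data, numbered 127. Of these, 126 (99.2%) were paired with a replicate peak that another peak was paired with too, against 4.41% of other peaks, which may be how they passed. Whether they are weak sites that would have passed on their own stays open: 0.787% had no other peak within 500 bp, but the sharing fixes this value, since 0 of the 332 sharing peaks had none. No biological explanation was tested. With 1 peak per replicate peak, 4630 peaks remained and the share of summits within 500 bp of a TSS was 40.9%.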
